A study of Mus musculus with 7 samples.

How the data were processed

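BACH1 occupancy was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) with an antibody against BACH1 in mouse lung tumor cell lines, 3 labelled mTC (control mice) and 3 labelled mTN (mice given NAC in the drinking water). Single-end reads came from a NextSeq instrument, per the labels' protocols. Reads were aligned to mm10 with BWA, per the submitters' processing notes, which give no version. The peak caller, the fragment extension, the scaling between libraries and the use of the input are not given in the sources used here. The labels list 7 libraries. The knockout library has no column in the table that was analysed, so the comparison of the knockout with its parent line was not run. The columns were matched to the libraries by the line names in their headers, and 0 columns of per-library values were left without a library.

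The authors deposited a table of merged regions, built from the intervals of all 6 libraries, with coordinates on mm10 and region lengths from 182 to 6388 bp. Coordinates are printed as the table gives them, and whether they count from 0 or 1 is not stated. Region numbers run to 6764 and 6283 regions were used, so 481 numbers were not analysed here. The file headers name an average and a peak value per library without saying what was measured. The values were read here as signal, the mean and maximum pileup over a region. Peak values were whole in 100% of cells, and average values multiplied by the number of bins of 32 bp came out whole (tolerance 0.0006 per bin) in 87.7% of regions. No read totals could be recovered from these values, so the depth per library is unknown and limits the precision to an unknown degree. Each library also has a call of 0 or 1 per region, the authors' own. The authors' deposited log2 ratio of mTN to mTC was recomputed from the average signals and differed by no more than rounding, with 3 cells not numeric. It was used only for this check. The authors' promoter count matched a window from 7500 bp upstream to 2500 bp downstream of the start of a listed gene in 99.3% of regions. Genes are those the authors list for a region, and 4170 of 4590 symbols matched the RefSeq table (GRCm38.p6) directly and 296 by an older name. That table gave the nearest gene where none was listed, and it does not tell introns from exons.

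Average signals were converted to log2(signal + 1), without further scaling. Regions with a mean signal over 6 libraries at or above the percentile 10 (7.42) were tested, 5655 in number. The difference between mTN and mTC was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, trend and robust off, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of weak regions. The prior degrees of freedom were infinite, so all regions shared a standard error of 0.509, and regions whose own spread is larger than average can pass more easily. Lists were tested with camera (preset correlation 0.01, and an estimated one) and fry. The share of list genes with a region was tested with one-sided Fisher exact tests and adjusted over 10 lists, against 21900 protein-coding genes. Values per library were compared with exact permutation tests over 20 assignments, and shares of regions with Fisher exact tests. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. No pair of libraries held identical values, with 0 identical pairs found.

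The region test was tested on simulated data with 5655 regions and 50 changed regions per size. For the comparison of mTN with mTC it recovered 2% of regions changed by 1 on the log2 scale, 18% at 1.5, 78% at 2 and 100% at 3, with 10 false calls among 109 (9.17%), above the nominal 5%. Adjusted p-values of the region test can thus be too small. With each library centred on its median the shares were 10%, 46%, 68% and 92%, with 4 false calls among 112 (3.57%). The simulation shuffled the spreads among regions and drew each region independently, whereas neighboring regions of the real data are not independent. These recovered and false shares therefore need not hold for the real regions.

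The groups, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The rule took 2 to 4 members of each list by highest mean signal, each gene standing by its strongest region, the 10 largest differences in each direction past the threshold, the 10 strongest regions, and the 5 strongest regions per group among those called in all lines of that group only. The lists were heme and iron, glutathione thioredoxin and NRF2 targets, BACH NRF and MAF regulators, glycolysis, pentose phosphate and NADPH, respiratory chain and mitochondria, AP-1, invasion and epithelial to mesenchymal transition, lung epithelium, and markers of other cell types. Together they hold 159 genes. Alternatives covered the pseudocount, the filter, centring and quantile normalization, peak signal, the variance model, the sex chromosomes, each line left out, and the line numbers as a block. Fits without mTC11 and mTN13, with chromosomes centred, with a block on centred values, and of promoter shares within 10 classes of region length were added after seeing the data. Lines 11 and 14 of the groups share numbers only, and the labels do not say that a number marks a shared animal or day. The titles give mTN13 and mTN14 the same index code, so the libraries may not all come from a single pool, and no batch is named. The motif search was not run because no genome sequence was used here.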

Results

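BACH1, a leucine zipper repressor that binds DNA with small MAF proteins and is removed when heme is plentiful, was mapped by chromatin immunoprecipitation and sequencing in mouse lung tumor cell lines driven by mutant Kras. There were 3 mTC lines, from control mice, and 3 mTN lines, from mice that received N-acetylcysteine (NAC), an antioxidant, in their drinking water. The design names them biological replicates, and each library came from a separate line. The deposited table held 6283 regions on mm10 with a median length of 370 bp, and gave for each library an average signal per region and a yes or no call. The number of reads behind each library is not given in the sources used here, so the depth is unknown. The median average signal was 7.67 in mTC11, 13.6 in mTC14, 15.7 in mTC31, 14.2 in mTN11, 9.46 in mTN13 and 14.1 in mTN14. A BACH1 knockout of the mTN11 line was not analysed here, so no value below is set against a library without BACH1.

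The strongest BACH1 signal of the table, 67.2 ± 13.6 over the 6 libraries (SD, n = 6), belonged to a region on chromosome 14 (67187905 to 67189322) with no gene listed, 43970 bp from Ebf2. The starts of Zmym6 and Fam21 followed with 67.1 and 63.0. The average signal was 60.2 ± 13.4 just upstream of Sqstm1, the autophagy receptor that also binds KEAP1. It was 58.6 ± 12.1 within Slc48a1, a heme transporter, and 59.9 ± 11 at the start of Mfsd1, a lysosomal membrane protein. The start of Clcn6, which encodes a chloride and proton exchanger of late endosomes, lay in a region with 56.7 ± 10.1 that also covered the upstream side of Mthfr. The other 3 of the 10 strongest regions lay 1715 bp from Sema4f, at the start of Cuta and 7067 bp from Trim56, with average signals of 57.7, 56.9 and 56.5. All 10 were called in all 6 libraries, and in limma none differed between mTC and mTN, with 0 of the 10 at an unadjusted p under 0.05.

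Regions called in every line lay at promoters more often than regions called in a single line. A total of 2476 regions (39.4%) were called in 1 library and 943 (15.0%) in all 6, with median average signals of 8.86 and 23.7. Of the 943, 387 (41.0%) overlapped a promoter, against 791 of the 2476 (31.9%). The odds ratio was 1.48 (two-sided Fisher exact test over regions, p = 7.17e-07). The regions called in all 6 were longer, with a median of 974 bp against 247 bp. Compared within 10 classes of region length, an alternative added after seeing the data, the odds ratio was 4.32 (permutation p = 5.0e-04, the smallest that the draws can give), although the shortest classes held hardly any region called in all 6. Over all 6283 regions 33.9% overlapped a promoter, 31.4% lay within a gene outside promoters, 28.3% had no gene listed and 23.3% held a CpG island. Neighboring regions are not independent, so this p describes the regions of these 6 libraries.

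Genes of glutathione and thioredoxin metabolism carried BACH1 regions far more often than other genes. At least 1 region was listed for 21 of the 25 genes of this NRF2 target list, against 3993 of 21900 protein-coding genes (18.2%) in the annotation (odds ratio 23.7, adjusted p = 1.70e-11, one-sided Fisher exact test over 10 lists). Gclm and Gclc, the subunits of the enzyme that begins glutathione synthesis, and the cystine transporter Slc7a11 had regions at percentiles 99.7, 99.5 and 98.7 of mean signal. The pentose phosphate and NADPH list had 7 of 8 genes with a region (adjusted p = 2.24e-04), the glycolysis list 10 of 21 (adjusted p = 0.00558), the list of BACH, NRF and MAF regulators 7 of 12 (adjusted p = 0.00558) and the heme and iron list 7 of 15 (adjusted p = 0.0218). No such excess passed for lung epithelium (6 of 20, adjusted p = 0.237), respiratory chain (4 of 14, adjusted p = 0.347), epithelial to mesenchymal transition and invasion (5 of 22, adjusted p = 0.466) or AP-1 (2 of 10, adjusted p = 0.632). Markers of fibroblasts, leukocytes and endothelium had a region at 1 of 12 genes (adjusted p = 0.911). That region is listed for Cd68 but lay 44 bp from Eif4a1, a translation factor gene, and 6519 bp from the start of Cd68. All lists counted every gene listed for a region, not only the nearest. In the glycolysis list, the strongest regions of Gpi1, Gapdh and Tpi1 had Garre1, Ncapd2 and Spsb2 as nearest genes. The Hk2 region lay 58140 bp from the start of Hk2. The comparison set held all protein-coding genes, active or not in these lines, and gene expression was not measured here. Proteasome subunit genes, a set outside these lists, had a region in 48.7% of cases, beside 47.6% for glycolysis and 46.7% for heme and iron. An excess of that size is thus not particular to these lists.

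The first question put to the groups was whether the antioxidant-exposed lines had more or less BACH1 signal at genes of redox and heme metabolism. None of the regions standing for list genes passed, and this answer covers the genes of the lists only. At Hmox1, the heme-degrading enzyme (chromosome 8, 75088435 to 75094187, upstream of the gene), the signal was 48.1 ± 23.5 in mTC and 62.3 ± 8.3 in mTN (SD, n = 3 each). At the ferritin genes it was 49.9 ± 17.4 and 62.0 ± 8.7 for Ftl1 (chromosome 7, 45459794 to 45461429, upstream), and 48.3 ± 17.6 and 37.3 ± 5.3 for Fth1 (chromosome 19, 9976561 to 9981279, upstream). For Sqstm1 the values were 55.2 ± 19 and 65.2 ± 3.8, for Gclm 48.3 ± 17.6 and 56.2 ± 12.3, for Gclc 42.0 ± 12.4 and 51.3 ± 4.6, and for Slc7a11 35.5 ± 8.8 and 42.8 ± 5.7. The library of line mTC11, whose signal was lowest over the whole table, gave the lowest value of the 6 at Hmox1, Ftl1, Sqstm1, Gclm, Gclc and Slc7a11. Nqo1, a quinone reductase named here after its values were seen, had 14.6 ± 2.9 in mTC and 7.24 ± 2.09 in mTN, without overlap of the lines (log2 difference -0.93, limma unadjusted p = 0.0663, adjusted p = 1.00).

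**Figure D1:**
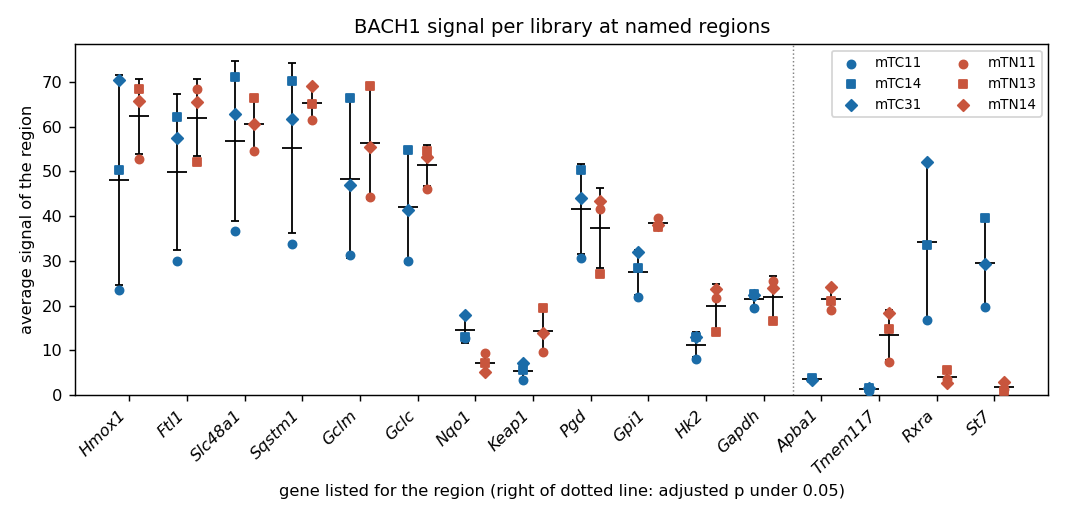
Average BACH1 signal (vertical axis, deposited units) of the region standing for each named gene, with mTC libraries in blue, mTN libraries in red, a marker shape per line, the group mean as a horizontal bar and the SD as an error bar (n = 3). The signal at Hmox1 was 48.1 in mTC and 62.3 in mTN with overlapping lines, whereas at St7 it was 29.5 and 1.81.

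Of the 12 regulators 7 had a region, and in limma 0 of the 7 passed between the groups. A region inside Bach1 (chromosome 16, 87712165 to 87713925) had 29.6 ± 11.1 in mTC and 23.5 ± 8.0 in mTN, and the region at Mafg, a small MAF partner, 22.1 ± 10.7 and 29.3 ± 5.1. At Keap1, the adaptor that targets NRF2 for degradation, the region was weak, with 5.46 ± 1.88 and 14.4 ± 4.9 (log2 difference 1.24, limma unadjusted p = 0.0145, adjusted p = 0.621). Keap1 was singled out after its values were seen, and its region was called in 1 of the 6 libraries. In the pentose phosphate list, Pgd had 41.6 ± 10.0 and 37.4 ± 9.0, and G6pdx, which encodes the entry enzyme of the pathway, 37.5 ± 10.6 and 36.6 ± 5.2.

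Among glycolysis genes, the region of Gpi1, glucose phosphate isomerase, was the strongest, with 27.5 ± 5.0 in mTC and 38.4 ± 1.0 in mTN (n = 3 each). The glucose transporter gene Slc2a1 had 23.7 ± 12.4 and 23.2 ± 2.5, Gapdh 21.5 ± 1.8 and 22 ± 4.8, and Pkm 18.1 ± 5.7 and 19.7 ± 6.3. Hk2, a hexokinase named after its values were seen, had a region downstream of the gene (chromosome 6, 82715949 to 82716680) with 11.3 ± 2.8 and 19.8 ± 5.1 (log2 difference 0.76, limma unadjusted p = 0.136). The lines of the groups did not overlap at Gpi1 and Hk2. Other genes lay closer to some of these regions: Ncapd2 was 145 bp from the Gapdh region, and the start of Gm12758 was nearer to the Gpi1 region than that of Gpi1. Regions of chromosome 6 as a whole, which carries Hk2 and Gapdh, had a median difference of 0.26 (mTN minus mTC, log2, libraries centred), and those of chromosome 7, which carries Gpi1, 0.10. Measured from the median of its chromosome on this scale, the difference was 0.42 at Hk2, 0.31 at Gpi1 and -0.33 at Gapdh.

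Tested as sets, no difference between mTN and mTC was detected for any of the lists. In limma's camera, 0 of the 9 lists that could be tested passed, 0 had an unadjusted p under 0.05, and the smallest adjusted p was 0.744. With an estimated correlation the smallest adjusted p was 0.987, and in fry, which asks whether a list moves on balance to one side, 0.898. Camera compares a list with the other regions, so a shift shared by all regions would not show in it. Of the 70 list genes with a tested region 0 passed over all regions tested and 2 had an unadjusted p under 0.05. The region test recovered 2% of simulated changes of 1 on the log2 scale, so differences of that size at single genes would mostly be missed. Adjusted over the list alone, 1 region was higher in mTN, at Atp5d of the respiratory chain list (7.22 ± 2.50 in mTC, 20.6 ± 6.5 in mTN, log2 difference 1.39, limma adjusted p over all regions = 0.410), and 0 in the other lists. This region lay inside Midn and 6495 bp from the start of Atp5d, and with each region given only to its nearest gene 0 passed in this list too. The groups did not overlap at 7 of the 70 genes (10.0%), beside 398 of the 5655 tested regions (7.04%), and chance gives 10% for 3 lines against 3. In the AP-1 list Fosl1 had 28.5 ± 6.7 in mTC and 26.0 ± 6.2 in mTN, and Junb 14.3 ± 4.4 and 9.85 ± 4.09. In the invasion list Cdh1 had 16.9 ± 4.4 and 19 ± 3.2, and Tgfb1 15.1 ± 4.1 and 20.1 ± 2.7. In the lung epithelium list Foxa1 had 16.1 ± 4.9 and 19.3 ± 4.7, and Etv5 10.4 ± 7.0 and 15.7 ± 3.5. The strongest gene of the respiratory chain list, Ndufc2, had 14.3 ± 6.6 and 14.2 ± 1.4, and the region listed for Cd68 9.67 ± 1.73 and 17.9 ± 7.2. List medians ran from -0.13 for AP-1 to 0.41 for the invasion list, beside 0.11 for all 5655 tested regions. These medians moved with single lines. Without mTC14 the AP-1 median was 0.03, and without mTC11 the invasion median was 0.22 and that of all tested regions -0.15. The pentose phosphate list had a median and mean above 0 with a camera direction below, and the AP-1 list a median and camera direction below 0 with a mean above.

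Over all regions, 34 of 5655 differed between the groups at an adjusted p of 0.05 in limma, 7 higher and 27 lower in mTN, and 250 had an unadjusted p under 0.05. The clearest decrease was inside St7, a gene named as a suppressor of tumorigenicity (chromosome 6, 17793214 to 17793784), from 29.5 ± 10.0 in mTC to 1.81 ± 1.01 in mTN (log2 difference -3.44, adjusted p = 3.80e-08, n = 3 each). A region inside Rxra, the retinoid X receptor (chromosome 2, 27738647 to 27741512), fell from 34.2 ± 17.7 to 4.00 ± 1.57 (log2 difference -2.72, adjusted p = 1.00e-04). Regions near the retinoic acid receptor gene Rarb (chromosome 14, 17084126 to 17084398), downstream of the adrenergic receptor gene Adrb2 (chromosome 18, 62169355 to 62169562) and within Disc1 (chromosome 8, 125254273 to 125254456) had log2 differences of -2.35, -2.54 and -2.26. They stayed past the threshold in 12 of 18, 10 of 17 and 7 of 17 alternative fits. Within Xist and Tsix, the RNA genes that control X inactivation, a region (chromosome X, 103481450 to 103481644) fell from 13.4 ± 4.3 to 1.94 ± 1.78 (log2 difference -2.50, adjusted p = 5.63e-04), and passed in 7 of 16 alternative fits, with adjusted p up to 1.00. The rest of the 10 largest decreases had no gene listed and lay on chromosomes 13, 2, 6 and 15 (log2 differences -3.13, -2.75, -2.54 and -2.30).

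The 7 regions higher in mTN were weak in mTC throughout. Inside Apba1, which encodes a neuronal adaptor protein (chromosome 19, 23846586 to 23848992), the signal rose from 3.72 ± 0.24 to 21.4 ± 2.6 (log2 difference 2.24, adjusted p = 0.00371, limma, n = 3 each). Inside Tmem117, a membrane protein gene (chromosome 15, 94817821 to 94818328), it rose from 1.41 ± 0.36 to 13.5 ± 5.6 (log2 difference 2.52, adjusted p = 5.31e-04). A region inside the RNA gene 2210019I11Rik (chromosome 5, 147243408 to 147244416), 25681 bp from Pdx1, had 5.22 ± 1.46 and 23.2 ± 5.9 (log2 difference 1.96, adjusted p = 0.0255). The regions of Apba1, Tmem117 and 2210019I11Rik stayed past the threshold in 13 of 19, 11 of 18 and 11 of 19 alternative fits. Regions with no gene listed on chromosomes 4, 7 and 1 had log2 differences of 2.45, 2.34 and 2.21. The lines of the groups overlapped at the chromosome 4 region, and the regions on chromosomes 4 and 7 each passed in 7 of 18 alternative fits and that on chromosome 1 in 8. The only Y region of the table (259044 to 259327) was listed at 0 in all 3 mTC libraries and had 17.2 ± 2.6 in mTN, so no fold is given for it.

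**Figure D2:**
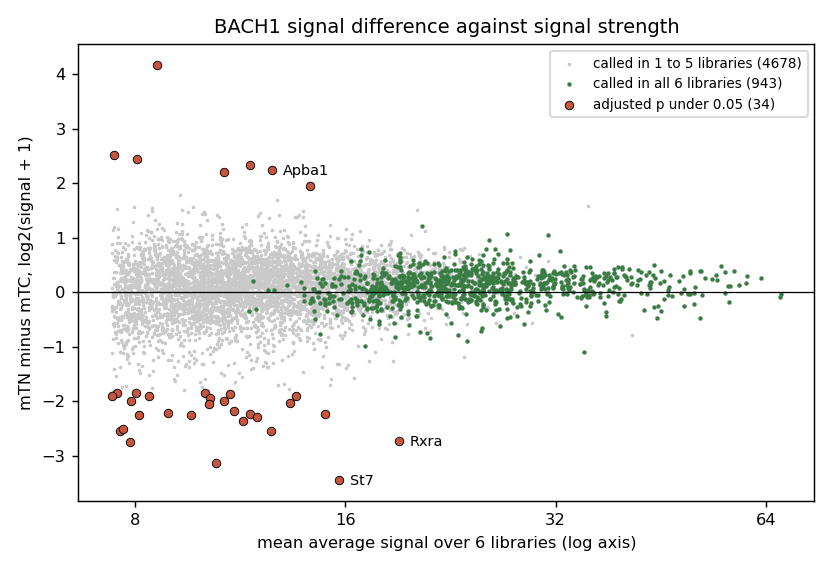
Difference of the mean log2(signal + 1) between mTN and mTC (vertical axis) against the mean average signal over 6 libraries (horizontal log axis) for the 5655 tested regions, with the 943 regions called in all 6 libraries in green and the 34 with an adjusted p under 0.05 in red. The 34 have a median signal of 10.3 over the libraries, with Rxra at 19.1, and 939 of the 943 lie between -1 and 1.

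None of the 34 was called in all 6 libraries, all 27 lower regions had no call in any mTN library, and all 7 higher regions had no call in any mTC library. Only 4 overlapped a promoter and 18 had no gene listed. Regions called in all 6 need signal in both groups, so a site lost in a group would not be among them. Of these 943 regions, 939 (99.6%) differed by less than 1 on the log2 scale, 0 passed in limma and 4 had an unadjusted p under 0.05. The count depended on single lines and on the variance model: 2 regions passed without mTC14, 8 without mTN14, 11 without mTC11, 17 without mTN13, 21 without mTC31, and 5 without both mTC11 and mTN13. With limma's trend and robust options 4 passed, 0 of them higher in mTN, and 1 higher region passed in each of the fits without mTC11, mTC14 or mTN14, while the St7 region passed under all 19 alternative settings and the Rxra region under 18.

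By calls alone, 57 regions were called in all 3 lines of a group and in none of the other, 24 in mTC and 33 in mTN. Of the 10 splits of the 6 libraries into 3 and 3, 5 gave 57 or more such regions, the real split included. The strongest of the mTC set were the regions in Rxra and St7, one in Glis3 (23.0 ± 1.6 in mTC, 9.00 ± 4.42 in mTN), one at Rgl2 and Tapbp (18.6 ± 3.2 and 13.2 ± 1.5) and one in Cntnap2 (19.7 ± 3.4 and 11.8 ± 5.5). The strongest region of the mTN set lay at the start of Mien1 (15.4 ± 2.4 in mTC, 25.7 ± 7.3 in mTN). It is also listed for Erbb2, a growth factor receptor gene, but lay downstream of that gene, and its nearest gene was Mien1. Next came the regions at Bsg (16.4 ± 2.1 and 20.6 ± 1.2) and at Emc1 and Mrto4 (12.4 ± 1.1 and 21.6 ± 0.1). Those at H1f0 and Gcat (13.5 ± 0.6 and 18.8 ± 2.7) and on chromosome 12 with no gene listed (12.6 ± 5.6 and 19.1 ± 3.3) followed. In limma the regions of Rxra and St7 passed the threshold and the other 8 did not (adjusted p of 0.410 for Glis3 and 1.00 for the rest). The count was 473 with a call in at least 2 of 3 lines, 21 with stricter calls, and 433 without mTC11 and mTN13.

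No difference in the amount of BACH1 signal as a whole was detected between the groups. The number of regions called was 1286 in mTC11, 3333 in mTC14, 3980 in mTC31, 3476 in mTN11, 2057 in mTN13 and 3407 in mTN14. This gave 2866 ± 1406 in mTC and 2980 ± 800 in mTN (SD, n = 3 each, two-sided exact permutation p = 0.8). The median log2 signal over the tested regions was 3.75 ± 0.48 and 3.83 ± 0.31 (difference 0.08, exact permutation p = 0.8). With 3 lines per group the exact test cannot go below p = 0.1. The scaling between libraries and the depth are unknown, so these values cannot tell whether BACH1 binding as a whole differed. Without mTC11 both differences turned negative, to -676.5 regions and -0.19, and without both mTC11 and mTN13 to -215 regions and -0.0171.

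The mean Pearson correlation of log2 signal across regions was 0.498 within mTC, 0.664 within mTN and 0.513 between groups, and regions are not independent replicates. Lines mTC11 and mTC14 correlated at 0.727, above all pairs between groups (up to 0.610), and each of them with mTC31 at 0.404 and 0.363. Line mTC31 correlated least with the others, at a mean of 0.398, while the other lines had means from 0.535 to 0.595. Differences also ran along chromosomes. After each library was centred on its median, the median difference (mTN minus mTC, log2) was -0.36 over the 336 tested regions of chromosome 13, -0.20 over chromosome 19 and 0.26 over chromosome 6. Chromosome 13 held 6 of the 27 lower regions, 2 of them inside Pde8b, a phosphodiesterase gene. On chromosome 2, line mTC31 lay 0.30 above its own median and the other 5 lines lay between -0.29 and -0.10. The lines of the groups did not overlap at 8 of 19 autosomes. Chance gives 10% for a single chromosome. The chromosomes come from the same 6 libraries and are not independent, so this count was not tested against chance.

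**Figure D3:**
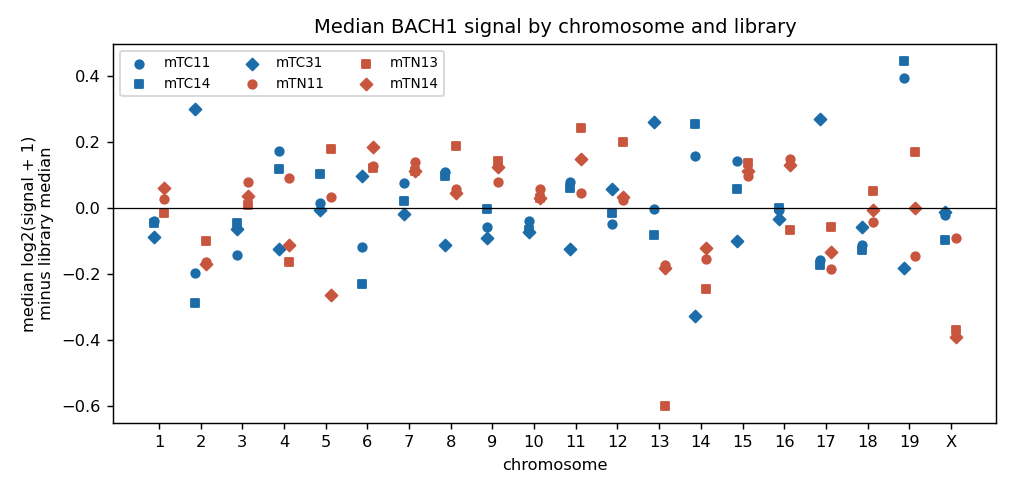
Median log2(signal + 1) of the tested regions of each chromosome minus the median of the same library (vertical axis), with mTC libraries in blue, mTN libraries in red and a marker shape per line. The mTN13 library sits at -0.60 on chromosome 13 and the mTC31 library at 0.30 on chromosome 2.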

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

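The fits without mTC11 and mTN13, with chromosomes centred, with a block on centred values and within length classes were chosen after the result was seen, and the rest was planned. The 34 regions became 36 with a pseudocount of 0.1 and 15 with 10, 35 without a filter and 13 with a filter at the median, 26 with median centring, 25 with quantile normalization, 36 with peak signal, 30 without X and Y, 25 with chromosomes centred and 4 with trend and robust, where the cause was not tested. Leaving out a line gave 2 to 25: 2 without mTC14, 8 without mTN14, 11 without mTC11, 17 without mTN13, 21 without mTC31, and 5 without both mTC11 and mTN13, with fewer libraries in the fit. The 7 higher regions numbered 0 with trend and robust, 1 without mTC11, mTC14, mTN14 or both mTC11 and mTN13, and 3 to 9 in the other fits without a block. Of the 34, 33 were shared at a pseudocount of 0.1, 21 after median centring and 10 without mTC11. With the line numbers as a replicate block, 40 passed, 23 higher and 17 lower, and 41 (4 and 37) on centred values. Lines whose number occurs in a single group add nothing to the difference in a fit with a block. Such a fit thus rests on lines 11 and 14 of each group, with 1 residual degree of freedom. The median difference over regions was 0.44 with the block, 0.01 with the block on centred values and 0.11 in the main fit. The alternative fits counted below include those with a block. The main fit left the lines unpaired, a choice made before the data were examined. The deviations of same-numbered lines correlated at -0.01 and -0.06. The 17 regions past the threshold that the text names by size stayed past it in 208 of 306 alternative fits, lost it in 98, and reversed in none.

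The difference in median signal ran from -0.19 to 0.26 when a line was left out (negative without mTC11, mTN11 or mTN14) and was -0.0171 without mTC11 and mTN13. The difference in regions called ran from -676.5 to 670.5, with the same lines giving negative values, and was -215 without mTC11 and mTN13. Both differences were small beside the spread of the lines. Regions called in all lines of a group only numbered 473 when 2 of 3 calls were enough, 21 with stricter calls, and 433 without mTC11 and mTN13, where fewer calls are required. The list tests passed 0 lists in every setting run. The promoter odds ratio stayed between 1.35 and 1.61 and was 4.32 within 10 classes of region length. The gap between correlations within and between groups was 0.07 and 0.05 with pseudocounts of 1 and 10. The DESeq2 and edgeR alternatives, the motif alternatives and the knockout comparison were not run. The values were read as signal and not as counts, and neither a genome nor a knockout column was used here. The unknown depth limits the comparison of weak regions.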

Other observations

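The limma counts over splits, the X and Y tests and the count of chromosomes that part the groups were chosen after the result was seen. The split counts of regions called on a side only were planned, but the rule for reading them was written after the result was seen. The other tests were fixed before their values were computed. The lysosome and proteasome lists were written after the strongest sites had been seen, and the comparison with mitochondrial ribosomal and initiation factor genes was added once the lysosomal share was known.

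Genes of the lysosome and of the proton pump that acidifies it carried BACH1 regions often, beyond those named among the strongest sites. Leaving out 7 genes noticed beforehand, 29 of 54 had a region (53.7%, exact binomial 95% interval 39.6 to 67.4), among them Lamp1, Ctsb, Ctsd, Npc1, Mcoln1 and Atp6v1a, against 18.2% of protein-coding genes (one-sided Fisher exact p = 4.67e-09). Proteasome subunit genes had a region in 19 of 39 cases (48.7%, adjusted p = 2.23e-05 over 8 tests), including Psma1, Psmb4 and Psmd12.

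Regions at lysosomal genes could mark constitutively active promoters. With promoter regions alone, ribosomal protein genes (16.9%, Fisher exact adjusted p = 0.0189) and mitochondrial ribosomal and initiation factor genes (25.2%, Fisher exact adjusted p = 8.81e-08) also lay above the 9.05% of all genes, so part of the excess may come from activity. Over all regions, ribosomal protein genes had a region in 16 of 83 cases, less often than lysosomal genes (Fisher exact p = 3.19e-05). So had mitochondrial ribosomal and initiation factor genes with 39 of 131 (Fisher exact p = 0.00201). Proteasome subunit genes came close to the lysosomal share, with 48.7% over all regions and 43.6% with promoter regions alone. Expression was not measured here, so activity as the whole source stays open. Gene length would raise the count too, yet with promoter regions alone the excess stood at 25 of 54 (Fisher exact p = 9.04e-13). A role of BACH1 at lysosomal and proteasomal genes is only a hypothesis from these data, in which neighboring genes share regions and no library without BACH1 was used. Proteasomal genes were not tested against the ribosomal or mitochondrial families.

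Differences between mTN and mTC shifted by chromosome, and medians of weak and strong regions of the 19 autosomes went together (Pearson r = 0.90, Spearman rho = 0.82, each with permutation p = 0.0001, the smallest that 9999 draws can give, and r = 0.83 without chromosomes 13 and 19), which is what copy number differences between tumor lines may produce. Broad chromatin differences would do the same and were not tested. An uneven spread of CpG island regions is argued against, since 99.9% of the spread of chromosome medians remained after centring by island class. Chance placement of local clusters is argued against too: the spread was 0.159, and the highest of 1000 shuffles of 5 Mb blocks gave 0.0811 (permutation p = 0.001, the smallest they can give). The groups parted at 8 of 19 autosomes, and the NAC exposure of the mice and the history of each line cannot be told apart with 3 separate lines per group.

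The Y region was listed at 0 in all mTC lines and the Xist region was lower in mTN. Whether mTC held a pair of equally bound X copies and mTN a single copy was asked of the 52 X regions. Their median difference was -0.0804 (95% bootstrap interval -0.35 to -0.01). That interval was drawn over regions and leaves out the spread between lines. The X medians of the centred libraries were -0.37 in mTN13, -0.39 in mTN14 and -0.09 in mTN11. In mTC11, mTC14 and mTC31 they were -0.02, -0.10 and -0.01. The X regions thus do not decide this question. The mTC lines may lack Y DNA, through female animals or loss of Y in the tumor or in culture. This rests on 1 region, with a lowest mTN signal of 14.6, and these sources cannot be told apart because the sex of the mice is not given in the sources used here. The Y region stayed past the threshold in 16 of 17 alternative fits and the Xist region in 7 of 16.

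Over the 10 splits of the 6 libraries into 3 and 3, only the real 1 gave as many as 34 regions, and the highest other gave 8. With 10 splits the share cannot fall under 0.05. For regions called in all libraries of a side only, 5 of the 10 splits gave 57 or more, and the highest gave 229. That split set mTC11, mTC14 and mTN13 against the rest and so placed the 2 libraries with the fewest calls on the same side, which points to a structure of the libraries. The other 3 splits with 57 or more also had mTC11 and mTN13 on the same side. The other splits set these libraries on opposite sides, as the real 1 does, and gave 9 to 31.

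Among regions called in all 6 libraries, mTC11 lay below the mean of the 4 libraries of higher signal by a median log2 ratio of -0.63 in the 189 weakest and -0.76 in the 189 strongest. For mTN13 the ratios were -0.40 and -0.26. The difference between strongest and weakest was -0.13 (95% bootstrap interval -0.24 to -0.03) for mTC11 and 0.14 (0.02 to 0.22) for mTN13. Differences of neighboring regions correlated across pairs at 0.28 for distances of 10 to 100 kb, 0.17 for 100 to 500 kb and 0.13 for 500 to 2000 kb.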
